A study of Homo sapiens with 6 samples.

How the data were processed

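Total RNA of MDA-MB-231 cells, an established human breast cancer line without oestrogen receptor and with mesenchymal features, was measured on 6 Affymetrix arrays. The cells had been infected with a lentivirus that carried a short hairpin against LOXL2 (shLOXL2, 3 arrays) or a control hairpin (shControl, 3 arrays). RNA was purified on RNeasy columns, amplified and biotin-labelled with a whole-transcript kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which match the knockdown field of every sample. For 2 of the 6 arrays, shControl replicates 2 and 3, the source name says shLOXL2 instead. These were kept as controls, and leaving them out was an alternative. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

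The values of each array were deposited on a log2 scale, and the submitters' processing notes name RMA, which corrects the background, normalizes between arrays and summarises the probes of a probe set. The RMA version, the genome build and the probe annotation are not given in the sources used here. The table held 32321 probe sets, identified by number alone, and no source used here paired these numbers with genes. The median log2 value of an array lay between 5.74 and 5.82. The number of arrays limits the precision, and the values carry no detection call.

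A second deposited table gave the authors' log ratio for 724 entries with gene symbols. Per its header it was exported from software of Ingenuity Systems. The header states no log base, no direction and no rule of selection. Decimal commas were converted, and the question mark before 312 entries was read as a minus sign, which put all 724 entries in falling order with 0 breaks. The direction was taken as shLOXL2 over shControl, because LOXL2, the target of the hairpin, had the lowest entry. The scale was taken as log2, which the data favour and do not settle. Log2 group differences of the value table were ranked and divided by the ranked entries. Their median ratio was 1.05 (higher side) and 1.09 (lower side) without the first 4090 probe sets, which are numbered almost without gaps, and 1.12 and 1.30 with all probe sets. Entries in log2 would give 1 and entries in natural logs 1.44, if the same probe sets had been ranked. The log ratios were not the plain group means of the value table. At a tolerance of 0.00051, 536 entries met some probe set's difference, and 20 shifted copies of the entries met 511 to 545. The same match was run for 51 combinations of arrays (means over each choice of arrays, group medians, and the median of the numbered pairs). For 1 of the 51 the number of matches was above those of all its shifted copies, by a single entry (630 against at most 629). Probe sets were therefore not named by value. Entries were named through RefSeq gene symbols (assembly GRCh38.p14, used for names, neighbours and host genes only). A file symbol was taken if it is a current symbol, or an older one that the table's own symbol column repeats or gives as a family. A first version of this rule accepted any synonym and misnamed some entries. It was made stricter after the first list results had been seen, which took the list genes in the table to 138 and the lists with at least 5 of them to 12. Of the 724 entries, 694 matched, to 650 genes, and 30 were left unnamed. Several entries of a gene were averaged. One gene, TIMP2, had entries of both signs and was left out of counts.

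The test planned before the data were examined was a limma fit across named genes. Because the probe sets had no names, limma (version 3.58.1, R 4.3.3) was fitted to all 32321 probe sets of the 6 arrays with group as the only term, empirical Bayes moderation and Benjamini-Hochberg adjustment. Controls among the probe sets could not be told from others, so none was left out. A probe set was called at an adjusted p under 0.05. On simulated data with the fitted spread of these arrays, among 32321 probe sets, the fit recovered 2% of 50 probe sets changed by 1.5-fold, 46% of 50 changed by 1 on the log2 scale, 94% of 50 changed by 2 and 100% of 50 changed by 3, with 9 false calls. An earlier simulation drew its spread from shrunken values, was too uniform and was replaced.

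The replicate numbers were checked for pairing before calls were compared. Deviations from the group means correlated across probe sets between same-numbered arrays (0.354, 0.452 and 0.160 for replicates 1, 2 and 3). The numbers were thus taken as pairs, by the data and not by the labels, and the fit with the replicate number as a block was an alternative.

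Gene groups were 35 lists (1031 genes) fixed before the data were examined. The planned set tests on the arrays (camera, fry) need named probe sets and were not run. Each list was instead counted in the authors' table. For the 12 lists with at least 5 genes there, the share listed higher was compared with that of the table's other genes by a two-sided Fisher's exact test. The share of each list that was in the table was compared with that of the other lists' genes in the same way, which assumes that all were measured. A list gene whose symbol holds the letters NA counts as absent unless an older symbol matched, since no identifier of that table holds them. Both were adjusted over the lists by Benjamini-Hochberg (scipy 1.17.1, statsmodels 0.14.6). Genes were treated as independent, which genes of a pathway are not, and the table had been selected by the authors, so these p-values describe the table and carry no replicate error. On 200 simulated tables these tests called a list with 15 of 15 genes in one direction in 100% of tables, and an unadjusted p under 0.05 came up for 2.78% and 3.90% of unrelated lists.

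The genes named in the text are LOXL2, the 5 genes at each end of the authors' table and, in each list described, up to 4 members. Members were to be chosen by p, and by size of the log ratio here, since the table has no p. Other genes named were chosen after their values were seen, and the text says so. CDH1, VIM and SNAI1 were to be named whatever their values; no value for them was analysed here. No identifier of the authors' table holds the letter pair NA, so an entry of SNAI1 could not have been matched by that symbol. Some members that this rule would name are not reported here. Alternatives were other normalizations, filters on dim probe sets, other variance priors, array weights, the replicate block, each array left out, and other ways of counting the lists.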

Results

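Expression was compared between MDA-MB-231 cells with a hairpin against LOXL2 and cells with a control hairpin, with 3 arrays in each group. LOXL2 is a secreted copper amine oxidase that oxidises lysines in collagen and elastin, and a nuclear role has also been described for it. The comparison asks which transcripts differ when LOXL2 is reduced in a mesenchymal breast cancer line. The values were of separate kinds, namely log2 values of 32321 unnamed probe sets on each array, and the authors' deposited table of log ratios for named genes. The first has replicates and no gene names. The second has gene names and no replicate error, so its values are given as listed, with no SD or n.

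LOXL2, the target of the hairpin, had the lowest value in the authors' deposited table, a log ratio of -3.04. If log2, this entry of the authors' deposited table is 8.22-fold lower in shLOXL2 cells, and no other gene there was as far from 0. The sign of the table was itself read from LOXL2, so its direction is no independent check of the knockdown. LOX, LOXL1, LOXL3 and LOXL4, the other members of the family, had no value analysed here. On the arrays, the largest fall of all probe sets was that of probe set 8149774, whose gene is not named in the sources used here. It measured 8.08 ± 0.22 (SD, n = 3) in shLOXL2 and 11.16 ± 0.21 (SD, n = 3) in shControl cells. The difference was -3.08 on the log2 scale (SE 0.167, 95% interval -3.47 to -2.68), or 8.43-fold lower, with an adjusted p of 0.0126 by limma. The next lowest difference of any probe set was -2.13. The values of single arrays were 8.27, 8.14 and 7.84 in shLOXL2 and 11.38, 10.96 and 11.14 in shControl replicates 1, 2 and 3. This probe set was picked by its difference between the groups as titled, so its values do not check the contradictory source name of 2 control arrays, replicates 2 and 3. Over all probe sets, shControl replicates 2 and 3 correlated at 0.979 and 0.978 with shControl replicate 1. With the same-numbered shLOXL2 arrays they correlated more, at 0.991 and 0.987, and with each other at 0.984. That order was not particular to these 2 arrays. shControl replicate 1 also correlated more with shLOXL2 replicate 1 (0.981) than with either other control. shLOXL2 replicate 2 did so with shControl replicate 2 (0.991, against 0.9821 and 0.9865 in its group). shLOXL2 replicate 1 did not (0.981, against 0.9821 and 0.9865).

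That probe set was the only one of the 32321 that passed an adjusted p of 0.05 by limma, so 0 probe sets were called higher and 1 was called lower. At an unadjusted p under 0.05 there were 1781 probe sets, 777 higher and 1004 lower, where 1616 would be found by chance. That balance turned to 920 higher and 815 lower with each array centred on its median, and was 851 and 912 after quantile normalization. With the replicate number as a block, the same probe set was again the only call (adjusted p = 0.0238 by limma), and 2964 probe sets had an unadjusted p under 0.05. The probe set with the next lowest p, 7979260, had a difference of -1.06 (SE 0.106), with an adjusted p of 0.363 by limma. Among probe sets with higher values the lowest p were those of 8117630, at 1.44 (SE 0.187), and 7896568, at 1.17 (SE 0.165). Both had an adjusted p of 0.547 by limma and did not pass. Probe set 7896568 was dim, with values of 2.50 to 4.10, below the lower quartile of every array (4.19 to 4.32). When any 1 array was left out, the difference of probe set 8149774 stayed between -3.18 and -2.95, and 0 probe sets passed in limma (adjusted p of this probe set 0.0822 to 0.149; 1063 to 2250 probe sets at an unadjusted p under 0.05). Changes of 1.5-fold were rarely detectable with this number of arrays, since 2% of them were recovered in simulated data. Of changes of 1 and 2 on the log2 scale, 46% and 94% were recovered there. The simulated values were independent and held no replicate pairs. They also held 50 changed probe sets at each size, many of them recovered, which eases the adjusted threshold. On the arrays 1 probe set passed, so these shares may overstate what could be detected there.

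**Figure D1:**
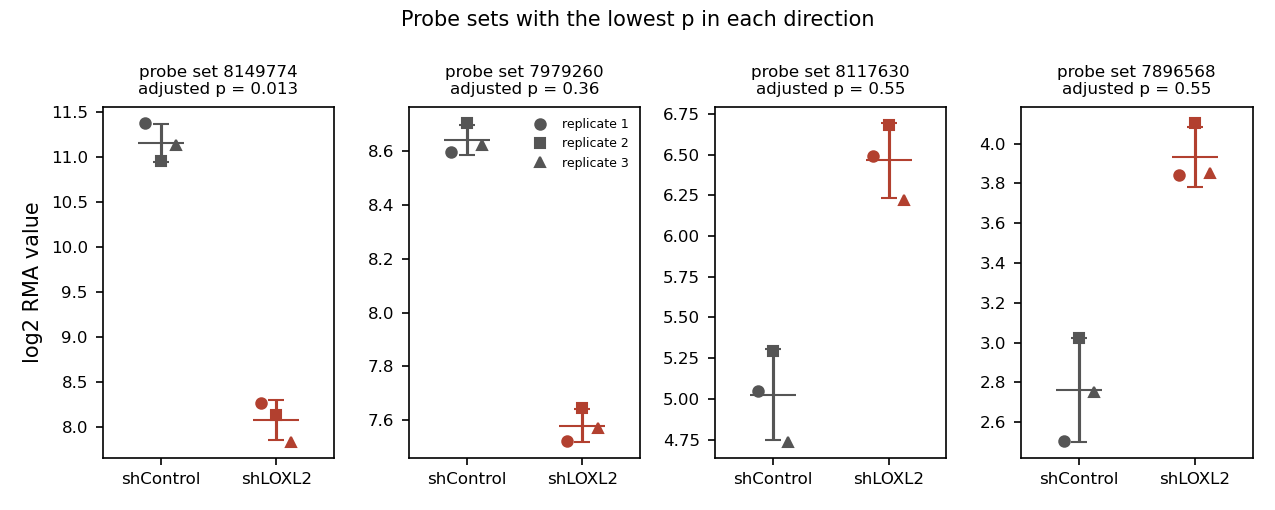
Log2 RMA values (vertical axis, a separate scale for each panel) of the 2 lowest-p probe sets that were lower and the 2 that were higher in shLOXL2 cells; points are the 3 arrays of each group, horizontal bars the means and whiskers the SD. Only probe set 8149774, with means of 11.16 and 8.08, passed the adjusted threshold. Probe set 7896568 (2.50 to 4.10) lay below the lower quartile of every array.

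The authors' deposited table held 724 entries, 412 listed higher and 312 listed lower in shLOXL2 cells, and no entry was smaller than 0.537 in size (1.45-fold if log2). The median size in the authors' deposited table was 0.652, and 67 entries reached 1 or more. The entries of the authors' deposited table came to 373 genes listed higher and 276 listed lower. Its 5 highest genes, by the authors' deposited table, were CXCL10, a chemokine that attracts T cells, at 1.84, COX7C, a subunit of cytochrome c oxidase, at 1.57, the membrane traffic protein MAL2 at 1.54, the zinc finger gene ZNF165 at 1.42 and the mitotic kinesin KIF20A at 1.39. After LOXL2, the lowest genes in the authors' deposited table were NEGR1, a neuronal adhesion molecule, at -1.38, the olfactory receptor OR5P2 at -1.30 and the keratin-associated proteins KRTAP2-4 at -1.30 and KRTAP2-1 at -1.29. The KRTAP2 genes are close in sequence, and KRTAP2-4 has 4 entries in the authors' deposited table, the lowest at -1.60. On the arrays, 1322 probe sets had a mean difference of 0.537 or more, 608 higher and 714 lower, and 1 of them passed the limma test. That balance turned to 719 and 622 with each array centred on its median, 659 and 656 after quantile normalization, 486 and 418 without the first numbered probe sets, and 421 and 367 above the median level. The count was 2158 (1036 higher, 1122 lower) without shLOXL2 replicate 2, 2003 (1029 and 974) without shControl replicate 2 and 2114 (813 and 1301) without shControl replicate 3.

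Genes of G2 phase and mitosis formed the largest of the groups examined. Of 56 list genes, 40 were in the authors' deposited table, all 40 listed higher, with a median log ratio of 0.79. In the authors' deposited table KIF20A had 1.39, CCNB2, a mitotic cyclin, 1.34, CDK1, the kinase that drives entry into mitosis, 1.20 and the centrosomal kinase NEK2 1.18. In the authors' deposited table, 54.7% of the other genes were listed higher (Fisher's exact test, two-sided, adjusted p = 1.24e-09). The authors' deposited table held 71.4% of the mitotic list and 10.1% of the other lists' genes (Fisher's exact test, adjusted p = 1.32e-23). Of 52 genes of G1/S transition and DNA replication, 4 were in the authors' deposited table, all listed higher, namely TK1, thymidine kinase, at 0.75, E2F8 at 0.61, PRIM1 at 0.58 and RFC4 at 0.56. This share of 7.69% in the authors' deposited table was lower than that of the mitotic list (Fisher's exact test, two-sided, p = 3.60e-12).

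Histone genes were likewise listed in one direction. Of 56 list genes, 20 were in the authors' deposited table, all 20 listed higher, with a median of 0.66 (Fisher's exact test on direction, adjusted p = 0.000138). The authors' deposited table held 35.7% of the list against 12.1% of the other lists' genes (Fisher's exact test, adjusted p = 0.000182). HIST1H4C had 1.09 in the authors' deposited table, the variant H2AFZ 0.84, HIST1H3B 0.80 and HIST1H4B 0.78. Histone genes of a family are close in sequence, so the 20 are not 20 separate measurements.

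Inflammatory genes were mostly listed higher and did not pass the test on direction. Of 39 NF-kB targets and cytokines, 11 were in the authors' deposited table, 10 of them listed higher (Fisher's exact test, adjusted p = 0.0694). The chemokines CXCL10, CXCL11 and CCL20 had 1.84, 1.35 and 1.29 in the authors' deposited table, and the apoptosis inhibitor BIRC3 had 1.28. IL11, a cytokine of the IL6 family, was the one listed lower, at -0.75 in the authors' deposited table. Of 48 interferon-stimulated genes, 6 were in the authors' deposited table, all 6 listed higher (Fisher's exact test, adjusted p = 0.0823). IFIT1 had 0.62 in the authors' deposited table, USP18 0.61, IRF1 0.59 and BST2 0.58. No higher share was possible (Fisher's exact test, unadjusted p = 0.0412), so 6 genes could not pass in this direction beside the other lists' p-values. Lists of 5 genes all listed lower could pass (unadjusted p = 0.0136), since fewer genes were listed lower (276) than higher (373). The share of the interferon list in the authors' deposited table was 12.5% against 13.4% of the other lists' genes (Fisher's exact test, adjusted p = 1), and passed against all other protein-coding genes, at 3.00% (adjusted p = 0.00986). The share of NF-kB targets in the authors' deposited table, 28.2% against 12.8%, did not pass either (Fisher's exact test, adjusted p = 0.0766), and passed under 3 of 5 other ways of counting.

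Targets of the transcriptional co-activator YAP and genes induced by MAPK signalling were listed lower. Of 24 YAP/TEAD targets, 5 were in the authors' deposited table, all listed lower (Fisher's exact test, adjusted p = 0.0409). In the authors' deposited table the matricellular genes CTGF (CCN2) and CYR61 (CCN1) had -1.23 and -1.09, ANKRD1 -0.97 and TGFB2 -0.83. Of 31 MAPK output genes, 5 were in the authors' deposited table, all listed lower as well (Fisher's exact test, adjusted p = 0.0409). The EGF receptor ligand HBEGF had -1.13 in the authors' deposited table, the immediate early gene EGR1 -0.97, the phosphatase gene DUSP1 -0.93 and IL11 -0.75. Both calls ended, at an adjusted p of 0.0739 by Fisher's exact test, when the mitotic and histone genes were left out of the comparison. Among genes at or above the table's median size, 4 MAPK genes were left, too few for the test. The YAP call held there (Fisher's exact test, adjusted p = 0.0269). The share of either list in the authors' deposited table did not pass (20.8%, adjusted p = 0.691, and 16.1%, adjusted p = 0.757, by Fisher's exact test). Against all other protein-coding genes both shares passed (Fisher's exact test, adjusted p = 0.00381 and 0.00768).

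Genes of the matrix and of adhesion showed no direction that passed, nor did their shares pass against the other lists' genes. Of 52 collagen and matrix genes, 6 were in the authors' deposited table, 5 listed lower and 1 higher (Fisher's exact test, adjusted p = 0.133). Beside CTGF and CYR61, the adhesive glycoprotein THBS1 had -0.84 and the collagen gene COL12A1 -0.77 in the authors' deposited table. Of 38 matrix proteases and inhibitors, 6 were in the authors' deposited table, 5 listed lower and 1 higher (Fisher's exact test, adjusted p = 0.133). ADAMTS12 had -0.87 in the authors' deposited table, ADAMTS6 -0.84 and PLAT, a plasminogen activator, -0.75. Of the TGF-beta targets in the authors' deposited table, 4 were listed lower and 1 higher (Fisher's exact test, adjusted p = 0.225), with INHBA at -0.72 beside CTGF and TGFB2. The 4 focal adhesion genes in the authors' deposited table were listed lower, namely CAV1 at -0.98, ITGA2 at -0.65, ITGA6 at -0.63 and PXN at -0.61, and were too few for the test on direction. Against all other protein-coding genes the shares of these 4 lists passed (Fisher's exact test, adjusted p = 0.0125 for matrix, 0.00450 for protease, 0.00734 for TGF-beta and 0.0422 for focal adhesion genes).

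Genes of epithelial junctions and polarity did not pass on direction. Of 46 such genes, 7 were in the authors' deposited table, 6 listed higher and 1 lower (Fisher's exact test, adjusted p = 0.298). Their share of 15.2% in the authors' deposited table passed against all other protein-coding genes (2.99%, Fisher's exact test, adjusted p = 0.00299) and not against the other lists' genes (13.3%, adjusted p = 0.769). The junction proteins MARVELD2 and CLDN4 had 0.98 and 0.81 in the authors' deposited table, the epithelial transcription factor ELF3 had 0.75, and the desmosomal cadherin DSC2 had -0.73. Of 32 mesenchymal genes and regulators of the epithelial to mesenchymal transition, 2 were in the authors' deposited table, both listed lower, among them TNC, a matrix glycoprotein, at -0.91. None of 17 keratins was among the entries analysed. Of 24 genes associated with metastasis of this line, 8 were in the authors' deposited table, 3 listed higher and 5 lower (Fisher's exact test, adjusted p = 0.322). Their share in the authors' deposited table, 33.3% against 12.9%, did not pass (Fisher's exact test, adjusted p = 0.0661), and passed under 3 of 5 other ways of counting.

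**Figure D2:**
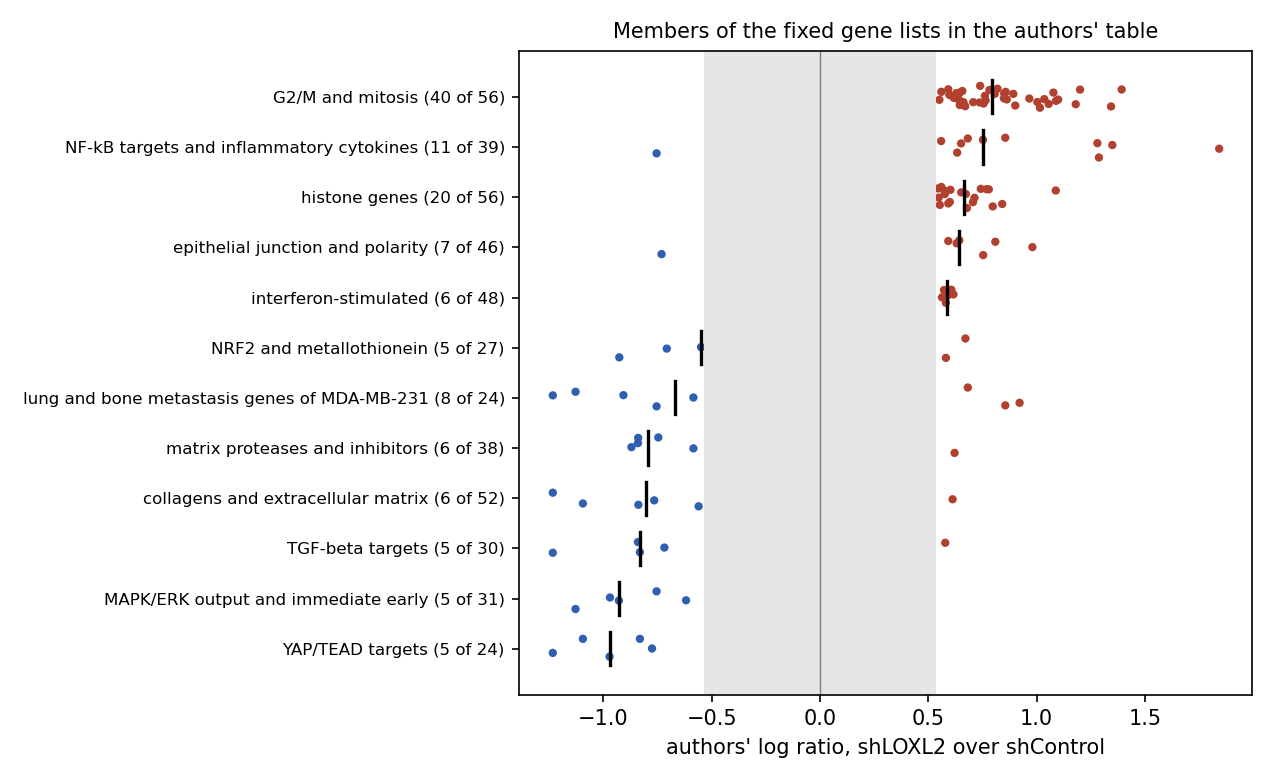
Authors' log ratios (horizontal axis, shLOXL2 over shControl) of the members of the 12 gene lists with at least 5 genes in the authors' deposited table, 1 point per gene, red for higher and blue for lower, with the list median as a black bar; the number of list genes in the table stands beside each name. The grey band holds no entries, since the smallest entry is 0.537 in size, and all 40 mitotic and all 20 histone genes lie on the higher side, all 5 YAP/TEAD targets on the lower.

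Metallothionein and NRF2 genes in the authors' deposited table were listed higher in 2 cases and lower in 3 (Fisher's exact test, adjusted p = 0.655), and their share passed only against all other protein-coding genes (adjusted p = 0.00504). MT1E had -0.93 in the authors' deposited table, MT1A -0.71 and NQO1 0.67. Of 63 ribosomal protein genes 1 was in the authors' deposited table, RPS15 at 0.63, a smaller share than that of the other lists' genes (1.59% against 14.2%, Fisher's exact test, adjusted p = 0.0208). That difference ended under 3 of 5 other ways of counting. None of the 18 blood cell and 15 fibroblast markers of the fixed lists was among the entries analysed, and 1 of 13 endothelial markers was, KDR at -0.80 in the authors' deposited table. The other lists not described had fewer than 5 genes there.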

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

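The call of 1 probe set, also at 1.5-fold, and its fall held under quantile normalization, median centring, both filters on dim probe sets, trend and robust moderation, array weights, the replicate block (1 call; the block changed no other call) and, an alternative chosen after seeing the data, without the first, consecutively numbered probe sets. There were 0 calls in limma at an adjusted p under 0.01 (1781 probe sets at an unadjusted p under 0.05), with shControl replicate 1 alone as control (3975; the lone array was assumed to vary like the others) and with any 1 array left out (0 to 0 calls; 1063 to 2250). With the replicate block and replicate 1, 2 or 3 left out of both groups, also chosen after seeing the data, there were 0 to 0 calls (1894 to 3165). The adjusted p of the probe set ranged from 0.00462 to 0.382 over the alternatives. The fall stayed between -3.30 and -2.95 under all of these, so the calls were lost with the number of arrays and the smaller threshold, not with the size of the difference. The number of probe sets with a difference of the listed size, 1322, went to 788 with the probe sets below the median level left out, to 2158 without shLOXL2 replicate 2, to 2003 and 2114 without shControl replicate 2 and 3, to 4897 with shControl replicate 1 alone, and, with the block, to 2432 and 2260 without replicate 2 and 3 of both groups. Its split of 608 higher and 714 lower became 719 and 622 after median centring, 813 and 1301 without shControl replicate 3, and 799 and 1461 with the block and without replicate 3 of both groups. For the lists, all alternatives were chosen after seeing the data. The mitotic and histone lists kept both calls in all 4 that include their genes. Without their genes, 0 lists passed on direction in place of 4, and YAP and MAPK targets had an adjusted p of 0.0739 each by Fisher's exact test. Fewer higher genes were then left to compare with. Among genes at or above the median size 3 lists passed on direction, since 4 MAPK genes were too few to test. On presence, NF-kB targets passed among genes at or above the median size (0.0276), without mitotic and histone genes (0.00642) and against all protein-coding genes (1.59e-07), and so did the metastasis list (0.0276, 0.00750 and 2.78e-06). The ribosomal list lost its call in the same 3 (0.0506, 0.376 and 1). Against all protein-coding genes 14 lists passed on presence in place of 3. The 14 include YAP targets (0.00381), MAPK targets (0.00768) and the interferon list (0.00986), whose share then lay above and not below that of the other genes; the lists hold well-studied genes, and the cause was not tested. Settings fixed beforehand that need named probe sets (several probe sets per gene, set tests, single genes, LOXL2 per array) were not run.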

Other observations

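All tests of explanations in this part were chosen after the results were seen. Among genes outside the fixed lists, those of small nucleolar RNAs and microRNAs formed a group of one direction in the authors' deposited table. It named 16 and 8 of them, and all 24 were listed lower, from -0.55 to -0.92, whereas 40.3% of the other genes were. In the authors' deposited table they include SNORA36A at -0.92, MIRLET7A2 and MIR125B1 at -0.85 each and MIR181A2 at -0.81. RPPH1, the RNA of RNase P and a non-coding RNA of another class, was listed higher in the authors' deposited table, at 0.57. In the authors' deposited table, keratin-associated protein genes, a family of close sequences, were listed lower in 7 of 7 cases (-1.30 to -0.58). These genes were chosen after their values were seen, and their log ratios carry no replicate error.

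The mitotic genes were listed higher in 40 of 40 cases in the authors' deposited table. The general excess of higher entries does not account for it, since 54.7% of the other genes were listed higher. A rise of G1/S genes like that of mitotic genes is argued against, because 7.69% of the G1/S list was in the table against 71.4% of the mitotic list (Fisher's exact test, p = 3.60e-12), whereas a smaller rise of G1/S genes stays open and 35.7% of the histone genes, many of them expressed in S phase, were in the table and listed higher. Whether 1 replicate pair carried the difference cannot be told apart from a difference in all 3, since the probe sets are not named. The differences of the pairs were correlated over all probe sets, which are not independent replicates. The correlations were 0.269 for pairs 1 and 2, 0.136 for 1 and 3, and 0.0372 for 2 and 3. Among probe sets above the median level they were 0.389, 0.288 and 0.1985. An effect of the LOXL2 knockdown on mitotic genes stays open and was not tested.

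In the authors' deposited table, 10 of 11 NF-kB targets and inflammatory cytokines and 6 of 6 interferon-stimulated genes were listed higher. Neither list passed on direction (Fisher's exact test, adjusted p = 0.0694 and 0.0823). The interferon list could not have passed in the higher direction, since all 6 of its genes were already listed higher. A broad interferon response to the hairpin against LOXL2 cannot be told apart from one of a few genes. Both groups had been infected with a lentivirus, so a response to the virus common to both would not show as a difference. Other effects of that hairpin cannot be separated from those of reduced LOXL2 in this design, for this or any other list. No share was set before the count was seen, and the genes are not independent. The count also covers the fixed interferon list alone. CXCL10 and CXCL11, at 1.84 and 1.35 in the authors' deposited table, were counted among the NF-kB targets and not in that list. The share of the interferon list in the table was 12.5% (exact upper 95% limit 25.2%), above the 3.00% of all other protein-coding genes (Fisher's exact test, adjusted p = 0.00986). An effect of LOXL2 itself also stays open and was not tested.

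For the small RNAs, a change of 1 host transcript is argued against, since GAS5, the non-coding gene that holds the most, has 6 of the 24 and the other 18 lie in other hosts or in none. A lower yield of short RNA in the shLOXL2 preparations cannot be told apart from a change in the cells. The group was singled out because all 24 point one way, and genes of 1 host are not independent. Whether these entries measured the mature small RNAs or longer transcripts that contain them is not given in the sources used here. Of the 14 host genes of the small RNAs, 0 had an entry among those analysed, which excludes nothing. An effect of LOXL2 on small RNA genes stays open and untested.

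The number of called probe sets cannot be set against chance with 10 splits of 6 arrays, which give no share under 0.05. The real split gave 1 call, the highest other split also 1, and 2 of 10 splits gave as many, with and without the 1.5-fold limit. The other split with 1 call put shLOXL2 replicates 1 and 3 with shControl replicate 3. It parts 1 numbered pair, and the 3 other splits that part all 3 pairs gave 0 calls. Of the 4 splits that part all pairs, the real one had the most probe sets with a difference of the listed size, 1322 against 551, 670 and 902, and the most probe sets at an unadjusted p under 0.05 with the replicate block, 2964 against 649, 969 and 1525. Splits along the replicate numbers had up to 1975 with a difference of the listed size, more than the real one. Without the block, the real split had 1781 probe sets at an unadjusted p under 0.05. The others that part all pairs had 432, 730 and 1074, and splits along the replicate numbers had up to 2859.

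The first 4090 probe sets, numbered almost without gaps, had a median residual SD of 0.329, against 0.185 in the other 28231. They made up 12.7% of all probe sets and 31.6% of those with a difference of the listed size.

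None of the 724 identifiers in the authors' deposited table holds the letter pair NA, where 13.5 would at the share found in protein-coding symbols (1.86%, 373 of 20056; binomial probability of 0 is 1.25e-06). Of the 30 entries left unnamed, 12 become a single current symbol when NA is inserted, against at most 4 for any of 10 other letter pairs. For AA, which is 1 of the 12, the symbol column of the authors' deposited table gives TEAD1 instead, of which AA is a synonym, and the entry was left unnamed here.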
